A study of Drosophila melanogaster with 4 samples.

How the data were processed

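Gene expression was measured by Affymetrix array in wing imaginal discs dissected from 3rd-instar larvae of flies kept at 25 degrees. There are 4 genotypes with 1 array each: yw flies with en-Gal4 alone (control), with en-Gal4 and UAS-PI3K (PI3K), with en-Gal4 and UAS-Hdac3 RNAi (Hdac3 RNAi), and with en-Gal4 and both transgenes (PI3K plus Hdac3 RNAi). Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. Pooling of discs, animals per array, array batch and dates are not given in the sources used here. The number of arrays limits the precision of every value, and no replicate error exists.

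The values are intensity on a linear scale, as deposited by the authors, for 18952 probe sets per array. The submitters' processing notes name MAS5, with no version or settings. The 2% trimmed means of the deposited columns were 287 in control, 281 in PI3K, 283 in Hdac3 RNAi and 284 in PI3K plus Hdac3 RNAi, so the deposited columns do not share 1 trimmed mean. The medians were 29.8, 30.9, 30.4 and 30.7 in the same order. Detection calls were not used here.

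Of the 18952 probe sets, 183 are Affymetrix controls. The annotation supplied for the array's probes, dated 2016, gave 1 gene symbol to 13646 of the remaining 18769 probe sets, several symbols to 402 and none to 4721. Probe sets with several symbols or none were left out of the gene comparisons because their signal cannot be assigned to 1 gene. The 13646 probe sets name 11981 genes, of which 1094 have 2 or more probe sets. A gene took the values of its probe set with the highest mean. Symbols, chromosome names and gene spans were matched to the RefSeq gene table of Release 6, and no coordinates are printed. Among the transgene targets and the driver locus, only en is analysed here, and Hdac3 and the PI3K subunit genes are not analysed here.

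Each array was scaled so that its 2% trimmed mean over all probe sets equalled the mean of the 4 trimmed means. Values under a floor of 26.9 were raised to the floor and log2 was taken. The floor is the 90th percentile of the scaled values of 125 probe sets named for odorant and gustatory receptors, genes that wing discs have little reason to express. With this floor, 7540 genes were at or above it in control, 7698 in PI3K, 7597 in Hdac3 RNAi and 7614 in PI3K plus Hdac3 RNAi, or 62.9%, 64.3%, 63.4% and 63.6% of the named genes. Across the arrays, 7301 genes were at or above the floor on all 4 and 7940 on at least 1. A ratio against a value at the floor is a lower bound on the difference and is written as "at least". A value just above the floor is kept as measured, although the floor does not separate it from background.

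The design has 2 factors, and 5 comparisons were made: PI3K against control, Hdac3 RNAi against control, PI3K plus Hdac3 RNAi against control, against PI3K alone and against Hdac3 RNAi alone. The departure from additivity is the log2 effect of Hdac3 RNAi in PI3K discs minus its effect without PI3K. For each, genes at least 2-fold apart were counted among those at or above the floor on both arrays (on all 4 for the departure), and bounds were counted separately. No test was run on these ratios. The PI3K effect can be measured by 2 contrasts that share no array (PI3K against control, and PI3K plus Hdac3 RNAi against Hdac3 RNAi), and so can the Hdac3 effect. Counts that share an array can move together because of that array's noise, so their correlation is given beside the value that equal and independent noise on the arrays gives in simulation. The correlations are across genes, and genes are not independent replicates.

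An additive model with PI3K and Hdac3 RNAi as terms was fitted with limma over 7696 genes at or above the floor on at least 2 arrays, with eBayes and Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom per gene, which holds noise and any interaction together. It treats the 2 arrays that carry a transgene as stand-ins for replicates.

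Gene lists were fixed by name: 39 lists with 939 named members in all. They cover PI3K and TOR signalling, FOXO-responsive genes, growth and metabolism, cell cycle, stress and immunity, markers of tissues near the disc, wing patterning and Hedgehog, Notch and Hippo signalling, ecdysone and cuticle genes, and chromatin. A list's value is the median log2 ratio of its members at or above the floor on at least 1 array of the comparison. Its percentile is its place among the medians of 10000 random lists of the same size matched on mean level in 20 bins. A percentile describes these arrays and is not a test across animals. For 37 lists a percentile was computed; the histone list and the list of transgene-linked genes have 1 measured member each. In the FOXO-responsive list, the entry DOR was matched through an alternative symbol to Atg13, which is another gene; the list was kept as fixed and also read without Atg13.

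The genes named in the text follow a rule: the targeted and driver genes; the genes at least 2-fold apart the same way in both contrasts without a shared array; the 5 highest and 5 lowest ratios and the 3 largest bounds each way of each comparison; the 10 largest departures from additivity each way; and, within a list, members at least 2-fold apart (up to 4) or, where there are none, the 2 with the highest mean signal. Other genes are named with a statement that they were chosen after their values were seen. The grouping, floor, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

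The alternatives were quantile normalisation, no scaling, a floor at the 40th percentile of all scaled values (20.5), no floor (values under 1 set to 1), the mean over a gene's probe sets in place of the highest, and for limma an intensity trend in the prior. After seeing the data, a count without 34 fat body, salivary glue and digestive genes was added. The 34 genes are the fat body list and genes with Sgs, Jon or Lys symbols, so other transcripts of these tissues may remain. Random lists matched on gene span as well as level were also added, for every list outside the central 95% in any comparison or in the departure. Lists outside in PI3K against control were matched in the contrast without a shared array as well. The FOXO-responsive list without Atg13 was added too.

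The steps were tested on simulated data with the signal levels of these arrays and normal noise. The noise was set, as a robust spread by signal level, from the PI3K plus Hdac3 RNAi and Hdac3 RNAi arrays. This pair had the smallest SD of log2 differences (0.22), and 38 of its genes were at least 2-fold apart. For PI3K and control this SD was 0.30. No wide tails, no trend with gene span and no carried-over tissue were simulated, so the false call rates below hold for quieter data than PI3K against control. For PI3K against control, the 2-fold rule found 100% of 94 genes simulated with a log2 change of 1.5 and 2.20% of 91 genes with a change of 0.75, with 0 false calls among 96 calls over 7602 genes. For the limma fit of the PI3K effect, 99% of 100 genes were found at each of these 2 changes over 7817 genes. Of its 236 calls, 38 were false (16.1%), above the nominal rate, and with the intensity trend 8 of 206 were false (3.88%). For the lists, 11 of 200 unchanged lists fell outside the central 95% of random lists (5.5%) and the changed list reached percentile 100, over 7882 genes.

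RNA quality was read from the 3' to 5' ratios of the array's control probe sets, and hybridisation from 9 spike-in probe sets. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and limma 3.58.1 ran under R 4.3.3.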

Results

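Wing imaginal discs, the larval tissue that forms the adult wing and part of the thorax, were profiled on 4 arrays: control discs (en-Gal4 alone), discs overexpressing PI3K, discs with Hdac3 RNAi, and discs with both. The engrailed driver acts in the posterior compartment, so every array mixes cells with and without the transgenes. The series asks what loss of the histone deacetylase Hdac3 does to growth driven by PI3K. There is 1 array per genotype, so no difference could be held against a spread between replicates. All values are scaled intensities or log2 ratios, and probe sets of the same gene differed within a comparison by an SD of 0.15 to 0.24 log2.

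The RNAi target Hdac3 and the PI3K subunit genes are not analysed here, so the knockdown and the overexpression are taken from the labels and were not checked in the arrays. The driver gene engrailed (en), which specifies posterior identity, had an intensity of 1428 in control, 1150 in PI3K, 1281 in Hdac3 RNAi and 1376 in PI3K plus Hdac3 RNAi discs. Both en and inv are read by probe sets of the type that can match more than 1 transcript. The posterior signal hedgehog (hh) had 752, 801, 767 and 900.2 in the same order. Invected (inv), the neighbouring paralogue of en, differed far more: 49.99 in control against 227, 215 and 254 in the 3 genotypes that carry a UAS transgene. Zip102B, a zinc transporter of the ZIP family, followed the same pattern with 34.9 in control against 408, 525 and 512. The Osiris family gene Osi6 had 122 in control and was under the floor on the other 3 arrays, and acs had 148 in control against 54.2, 33.9 and 45.4. Because these genes set the control array apart from all 3 others, their ratios against control do not separate PI3K from Hdac3 RNAi.

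PI3K overexpression came with 63 genes at least 2-fold higher and 28 at least 2-fold lower than control, of 7436 genes at or above the floor on both arrays. A further 12 genes were at least 2-fold higher and 1 lower as bounds. Besides Zip102B, the highest were the salivary glue genes Sgs5 (log2 ratio 3.08) and Sgs3 (2.86), the odorant-binding protein gene Obp44a (3.02) and CG15369 (2.66). The lowest were the drosomycin-like gene Drsl2 (-1.60), CG10912 (-1.58), acs (-1.45), the axon guidance gene Sema1a (-1.33) and the RNA-binding protein gene shep (-1.32). Drsl2, CG10912 and acs were at least 2-fold lower in all 3 transgene genotypes than in control, so Drsl2 and acs do not single out PI3K. CG10912 was lower with PI3K in Hdac3-depleted discs as well, by a bound of -1.38. For shep the mean over its 4 probe sets was -0.38, so its ratio rests on 1 of them. Cyp4p2, a cytochrome P450, was under the floor in control and at 806 in PI3K discs, at least 4.90 log2 higher.

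Components of the PI3K and TOR pathway itself were lower in PI3K discs. The list's median log2 ratio was -0.28, percentile 0.02 of random lists, with 14 of 16 measured members negative. The insulin receptor InR, a gene that FOXO activates when insulin signalling is low, had 465 in control and 188 in PI3K discs, a log2 ratio of -1.31. Akt (-0.79) and S6k (-0.77), chosen after their values were seen, were lower as well. FOXO-responsive genes as a list had a median of -0.17 (percentile 1.35), with scyl at -0.77 and Pepck1 higher at 0.39. The list holds Atg13 by a symbol match to another gene, and without it the median was -0.19 (percentile 1.06).

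Genes of mitochondria and protein turnover were higher in PI3K discs by small amounts shared across nearly all members. Mitochondrial ribosomal proteins had a median of 0.24 (percentile 100), positive in 69 of 69 members, among them mRpL47 and mRpS21 (both 0.27). Proteasome subunits had a median of 0.16 (percentile 100; 28 of 30 positive), with Prosbeta3 at 0.19 and Prosbeta7 at 0.23. Oxidative phosphorylation had 0.14 (percentile 100; 53 of 57 positive), with ATPsynF at 0.11, and glycolysis 0.18 (percentile 99.7; 8 of 10 positive), with Tpi at 0.18 and Eno at 0.12. Amino acid transport and synthesis was higher (0.16, percentile 99.7), as were cytochrome P450s (0.18, percentile 99.9; Cyp6g1 and Cyp4d1 both 1.23), glutathione S-transferases (0.12, percentile 98.1; GstE3 1.64) and cuticle proteins (0.13, percentile 99.3; Cpr64Ac 2.10). Cytosolic ribosomal proteins (0.04, percentile 55.0), ribosome biogenesis (0.05, percentile 77.3), translation factors (0.05, percentile 69.97), lipid synthesis (0.06, percentile 73.3) and autophagy (0.03, percentile 58.0) lay within the central 95% of random lists.

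Wing patterning genes were lower in PI3K discs. The wing patterning list had a median of -0.35 (percentile 0), negative in 28 of 30 members, with the hinge gene zfh2 at -1.10 and the Dpp receptor tkv at -0.35. Anterior and Hedgehog-response genes had -0.40 (percentile 0.14), negative in all 6, with ci at -0.73. Dad, an inhibitor of Dpp signalling kept in this list as fixed, was at -0.31. The posterior list stayed within random lists (0.09, percentile 74.5), but it holds only 3 genes: en at -0.31, hh at 0.09 and inv at 2.18. Its median is the value of hh, and inv sets the control array apart. Hippo pathway genes (-0.19, percentile 0.35; 12 of 14 negative), Polycomb and trithorax genes (-0.19, percentile 0.08; 15 of 17 negative), Notch-responsive E(spl) genes (-0.17, percentile 1.88) and ecdysone-response genes (-0.12, percentile 1.0) were lower too, although the last list's Sgs3, Sgs4 and Fbp1 were higher. Adult muscle precursor markers (-0.35, percentile 0.12; kon -0.47), differentiated muscle markers (-0.37, percentile 0.03; sls -0.79) and hemocyte markers (-0.17, percentile 0.33; LanA -0.42) were lower, in tissue that adheres to or lies within the disc. Cell cycle lists lay within the central 95%: replication and S phase had -0.05 (percentile 10.5; PCNA 0.06) and G2 and mitosis -0.08 (percentile 2.85; Bub3 0.13).

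Within the central 95% in PI3K discs were apoptosis (0.07, percentile 80.1), JNK and wound response (-0.03, percentile 15.3), heat shock and chaperones (0.01, percentile 21.98), immune genes (-0.16, percentile 3.13), tracheal (-0.06, percentile 17.0) and neuron and glia markers (-0.06, percentile 11.2), proneural genes (-0.09, percentile 10.5), deacetylases and acetyltransferases (-0.07, percentile 13.7) and dosage compensation genes (-0.14, percentile 3.09). Single members still stood out, with the heat-inducible chaperone Hsp68 at -1.02, the antifungal peptide gene Drs at -1.12 and Sxl at -0.89. The variant histone gene His2Av, the 1 histone gene measured, was at -0.18. In all, 20 of 37 lists were outside the central 95% of random lists, against 1.85 by chance. The PI3K array also had lower 3' to 5' ratios than control, 2.02 against 3.36 for actin and 3.11 against 3.95 for eIF-4a. Across 7270 genes longer genes had lower log2 ratios (Spearman rho -0.46 with gene span), with a median of 0.11 in the quartile of shortest genes and -0.17 in that of the longest. Matched on span as well, 13 of the 20 lists stayed outside the central 95%, among them wing patterning (percentile 0.26), PI3K and TOR components (0.42), adult muscle precursor markers (2.38) and hemocyte markers (1.8). The 7 that did not were Hippo genes (25.9), ecdysone-response genes (28.5), FOXO-responsive genes (15.8), anterior genes (10.1), Polycomb and trithorax genes (3.96), glutathione S-transferases (83.6) and cuticle proteins (87.6).

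**Figure D1:**
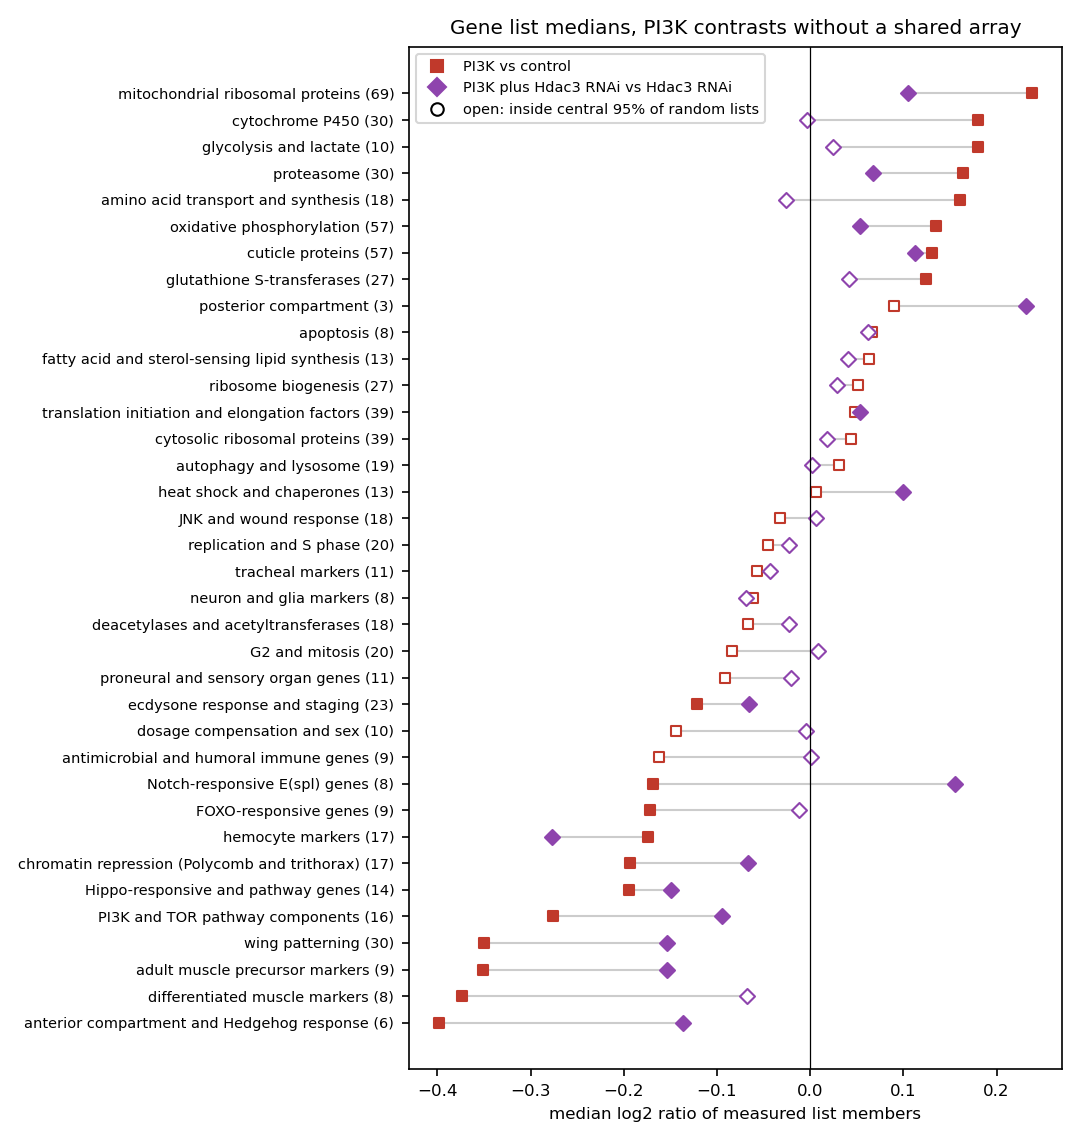
Median log2 ratio of 36 gene lists (measured members in brackets) in PI3K against control (squares) and in PI3K plus Hdac3 RNAi against Hdac3 RNAi (diamonds), which share no array; open symbols lie within the central 95% of random lists, and the fat body list is left out because it is off the scale. Mitochondrial ribosomal proteins lie above 0 in both (0.24 and 0.11) and wing patterning genes below 0 in both (-0.35 and -0.15).

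Fat body markers had the list median farthest from 0 in every comparison. They were higher in PI3K discs than in control (median log2 1.68, percentile 100), with Fbp2 at 3188 against 719, Lsp2 at 2358 against 622 and Obp99b at 5593 against 1189. These encode storage and carrier proteins of the larval fat body. They were also higher with Hdac3 RNAi alone (0.94, percentile 100; Fbp1 1.64) and lower with both transgenes (-1.24, percentile 0; Fbp2 -2.49). Of the list's 11 members, 9 were at or above the floor in control and 1 also belongs to another list. Salivary glue genes were highest in PI3K discs, with Sgs5 at 1441 against 171 in control, 176 in Hdac3 RNAi and 136 with both. The digestive protease gene Jon65Aiii had 515 in control, 1382 in PI3K, 391.9 in Hdac3 RNAi and 51.9 with both.

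**Figure D2:**
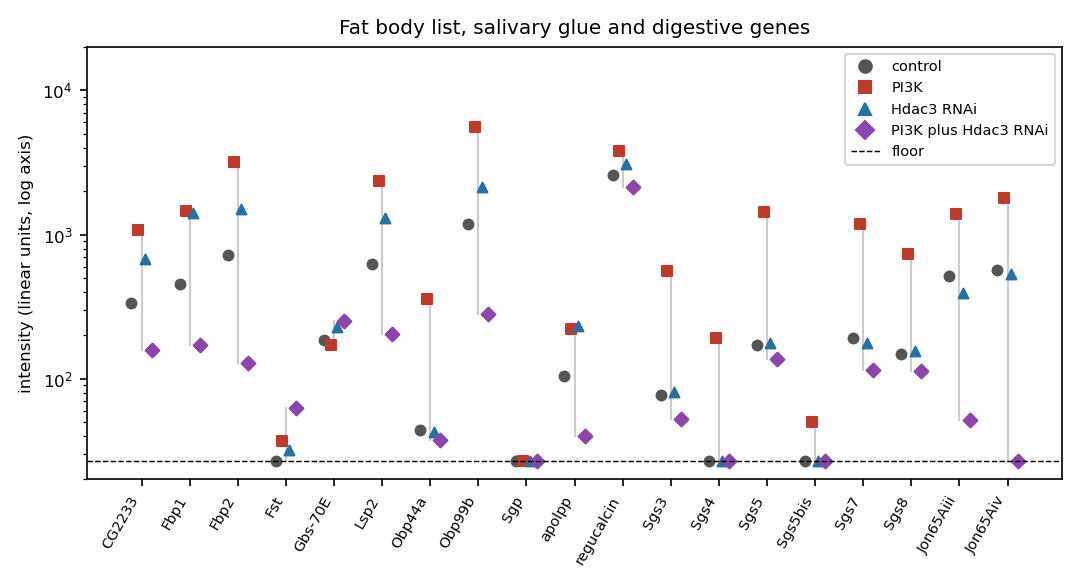
Intensity on a log scale of fat body, salivary glue and digestive genes on each of the 4 arrays, 1 point per gene and array. Fbp2 spans 128 to 3188 and Sgs5 136 to 1441, with the PI3K array highest for both.

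Hdac3 RNAi alone came with 20 genes at least 2-fold higher and 21 lower than control, of 7407 genes. The highest besides Zip102B and inv were CG9021 (2.95), CG34296 (2.45) and Fbp1 (1.64). The lowest were Ect3 (-2.34), acs (-2.12), the piRNA-pathway gene krimp (-1.81), the asparagine synthetase gene AsnS (-1.63) and Cpr64Ac (-1.57). Tektin-C, which encodes a filament protein of cilia and flagella, was under the floor in control and at 350.4 with Hdac3 RNAi, at least 3.70 log2 higher, and CG12773 was at least 2.67 higher. Drsl2, under the floor with Hdac3 RNAi, was lower by a bound of -2.07.

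Wing growth and patterning lists were slightly higher with Hdac3 RNAi alone, relative to the arrays' trimmed means. Wing patterning genes had a median of 0.11 (percentile 100; 22 of 30 positive; tkv 0.12), Hippo pathway genes 0.13 (percentile 99.95; 13 of 14 positive; crb 0.08) and anterior and Hedgehog-response genes 0.17 (percentile 99.6; 6 of 6 positive; ci 0.17). Tracheal markers had 0.24 (percentile 100), with obst-A at 0.44 and Gasp at 0.33, which encode chitin-binding proteins. Ribosome biogenesis (0.07, percentile 99.8; Nop60B 0.11) and PI3K and TOR components (0.06, percentile 98.1) were higher, and glutathione S-transferases lower (-0.10, percentile 0.63; 19 of 26 negative). The other lists, apart from fat body markers, stayed within the central 95%, deacetylases and acetyltransferases among them (-0.11, percentile 5.56), with HDAC1 at 0.18. The effect sizes are below the 2-fold rule, and 8 of 37 lists were outside against 1.85 by chance. The 9 spike-in probe sets had a median log2 ratio of 0.20 here, 0.03 in PI3K against control and 0.18 in discs with both transgenes against control. Apart from tracheal and fat body markers, every list called higher with Hdac3 RNAi has a smaller median than these spikes. The spikes are hybridisation controls and differ among themselves. With Hdac3 RNAi against control, bioB had 312 against 288 and bioD 4747 against 3957. They therefore give no baseline for the direction of a list. The percentiles do not depend on a shift common to all genes. Matched on gene span as well, 6 of the 8 lists stayed outside the central 95%, while PI3K and TOR components (92.9) and anterior genes (92.2) did not.

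With Hdac3 RNAi added to PI3K overexpression, 28 genes were at least 2-fold higher and 63 lower than with PI3K alone, of 7475. The highest were Tektin-C (3.78, from 27.9 with PI3K, next to the floor), Hsp68 (2.26), CG9021 (2.17), the RING finger gene Rnf11 (1.84) and CG33333 (1.75). Hsp68 had 378 with PI3K, 1810.3 with both and 768 in control. The lowest were Jon65Aiii (-4.73), Fbp2 (-4.64), CG8997 (-4.59), CG14302 (-4.57) and Obp99b (-4.31), with CG8997 (30.1) and CG14302 (28.5) next to the floor in discs with both, and Jon65Aiv was under the floor with both, a bound of -6.06. Without the fat body list and the Sgs, Jon and Lys genes, 48 genes were at least 2-fold lower and 28 higher. Genes under other names, such as CG8997 and CG14302, were kept, so the 48 may still hold transcripts of other tissues.

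Several lists that were lower with PI3K alone were higher when Hdac3 RNAi was added, and 18 of 37 lists were outside the central 95%. Wing patterning genes had a median of 0.39 against PI3K (percentile 100; 27 of 30 positive; zfh2 1.06), anterior and Hedgehog-response genes 0.55 (percentile 100; ci 0.70), Hippo genes 0.27 (percentile 99.97; 11 of 14 positive), PI3K and TOR components 0.20 (percentile 99.97; InR 1.05) and FOXO-responsive genes 0.20 (percentile 99.3; scyl 1.09). E(spl) genes had 0.28 (percentile 99.8), proneural genes 0.16 (percentile 98.9), Polycomb and trithorax genes 0.11 (percentile 99.2) and tracheal markers 0.26 (percentile 99.9). Mitochondrial ribosomal proteins had -0.16 (percentile 0; 66 of 69 negative; mRpS21 -0.22), oxidative phosphorylation -0.11 (percentile 0), glycolysis -0.20 (percentile 0.04; Eno -0.20), proteasome -0.09 (percentile 0.38), amino acid genes -0.17 (percentile 0.36; AsnS -1.27), glutathione S-transferases -0.17 (percentile 0.01; GstE3 -2.01) and P450s -0.14 (percentile 1.72; Cyp4d1 -1.36). Cuticle proteins were higher (0.08, percentile 99.9), although Cpr64Ac was at -2.66, and ImpL2, a secreted insulin-binding protein gene, was at -1.14. The medians of cuticle and of Polycomb and trithorax genes are below the spike-in median of 0.14.

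This reversal uses the PI3K array on both sides. Longer genes had higher ratios here (rho 0.33 with gene span), with a median of -0.06 in the quartile of shortest genes and 0.12 in that of the longest. Matched on span as well, 13 of the 18 lists stayed outside the central 95%, while Hippo genes (97.4), FOXO-responsive genes (93.045), Polycomb and trithorax genes (92.3), proteasome (7.56) and P450s (5.95) did not. Across 7301 genes the log2 ratio of PI3K against control and that of both transgenes against PI3K had a Pearson r of -0.75, where equal independent noise on the arrays gave -0.51 in simulation, and 57 genes were at least 2-fold apart in opposite directions with 0 in the same direction. The arrays were not equal in spread, however. The SD of log2 differences was 0.30 to 0.35 in pairs with the PI3K array and 0.22 to 0.23 in the others. A wider spread on the shared array alone would take r below -0.51, so the gap to -0.75 does not separate a reversal from noise. Part or all of the reversal may come from the shared array, whose 3' to 5' ratios were the lowest of the 4 for actin, GAPDH, eIF-4a and Act5C. A lower ratio means more 5' signal beside the 3' signal, so these controls do not mark the PI3K array as the most degraded. For 18S rRNA its ratio was the highest, 4.95 against 4.77 to 4.87 on the others.

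In discs with both transgenes, 15 genes were at least 2-fold higher and 37 lower than control, of 7397. The highest besides Zip102B and inv were CG33333 (1.91), CG9021 (1.76) and CG7465 (1.69), and Cyp4p2 and Tektin-C were at least 4.997 and 3.83 higher. The lowest were CG14302 (-3.82), Jon65Aiii (-3.31), Ect3 (-2.50), Fbp2 (-2.49) and yip7 (-2.21). Outside the central 95% were 19 of 37 lists. The wing patterning list was close to control (-0.01, percentile 53.6), as were PI3K and TOR components (-0.05, percentile 24.2), Hippo genes (0.02, percentile 83.2), oxidative phosphorylation (0.02, percentile 54.4) and glycolysis (-0.03, percentile 11.6). Mitochondrial ribosomal proteins (0.06, percentile 100), proteasome (0.08, percentile 99.1), ribosome biogenesis (0.09, percentile 99.98), translation factors (0.06, percentile 98.8), tracheal markers (0.17, percentile 99.97), E(spl) genes (0.14, percentile 99.6), posterior genes (0.26, percentile 99.8), anterior and Hedgehog-response genes (0.11, percentile 98.1) and cuticle proteins (0.11, percentile 99.97) were higher, and of these only posterior genes were above the spike-in median of 0.18. Hemocyte markers (-0.22, percentile 0; NimC1 -1.03), adult muscle precursor markers (-0.21, percentile 0.92; kon -0.21), differentiated muscle markers (-0.30, percentile 0.14; sls -0.26), immune genes (-0.18, percentile 0.32; Drs -1.07), S phase genes (-0.08, percentile 1.26), ecdysone-response genes (-0.11, percentile 0.39), neuron and glia markers (-0.13, percentile 2.13) and glutathione S-transferases (-0.07, percentile 1.4) were lower. Of the 3 posterior genes, hh was at 0.26, inv at 2.35 and en at -0.05. Hsp68 was at 1.24 and Cyp18a1, which inactivates ecdysone, at -1.25. P450s as a list were lower (-0.13, percentile 0.14), and without a floor their median was 0.0076. Matched on gene span as well, 13 of the 19 lists stayed outside the central 95%, while mitochondrial ribosomal proteins (86.2), proteasome (97.4), anterior genes (97.1), E(spl) genes (96.2), S phase genes (2.56) and neuron and glia markers (4.84) did not.

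Against Hdac3 RNAi alone, discs with both transgenes had 10 genes at least 2-fold higher and 28 lower, of 7456. The highest were Cyp4p2 (4.98, from 27.2 with Hdac3 RNAi, next to the floor), CG33333 (2.41), the odorant-binding protein gene Obp56d (1.92), CG7465 (1.47) and krimp (1.39). The lowest were CG14302 (-3.79), Fbp2 (-3.56), Fbp1 (-3.05), Jon65Aiii (-2.92) and Obp99b (-2.92). The gluconeogenic gene Pepck1 was at 0.95. This comparison gives the PI3K effect from arrays not used in PI3K against control, and some of the lists repeated. Mitochondrial ribosomal proteins had 0.11 (percentile 100; 64 of 69 positive; mRpS21 0.17), proteasome 0.07 (percentile 99.95; 29 of 30 positive) and oxidative phosphorylation 0.05 (percentile 99.6; 51 of 58 positive). Wing patterning had -0.15 (percentile 0; 23 of 30 negative; tkv -0.16), Hippo genes -0.15 (percentile 0.01; 14 of 14 negative), PI3K and TOR components -0.09 (percentile 0.28; 13 of 16 negative; path -0.12) and anterior genes -0.14 (percentile 0.72; ci -0.20). The 3 posterior genes were higher (0.23, percentile 99.2), with hh at 0.23, inv at 0.24 and en at 0.10. E(spl) genes were higher instead of lower (0.16, percentile 99.9; E(spl)mbeta-HLH 0.22), and hemocyte markers were lower (-0.28, percentile 0; srp -1.16). Within the central 95%, unlike in PI3K against control, were glycolysis (0.02, percentile 57.9), amino acid genes (-0.03, percentile 9.22), P450s (-0.0034, percentile 22.2), glutathione S-transferases (0.04, percentile 80.6), FOXO-responsive genes (-0.01, percentile 26.3, or 0.06 and 80.8 without Atg13) and differentiated muscle markers (-0.07, percentile 15.9). Longer genes had lower ratios here too (rho -0.26), and 17 of 37 lists were outside the central 95%. Matched on span as well 13 of the 17 stayed so, while oxidative phosphorylation (87.8), anterior genes (16.4), ecdysone-response genes (6.84) and Polycomb and trithorax genes (7.41) did not.

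Genes at least 2-fold apart in both contrasts that share no array are few. For the PI3K effect, 3 of 7301 genes were higher in both, where independent lists of 55 and 9 genes would share 0.0678: Obp56d (1.61 and 1.92), Cpr64Ac (2.10 and 1.01) and CG32055 (1.04 and 1.06). Drs was the 1 gene lower in both (-1.12 and -2.04), against 0.092 for lists of 24 and 28, and 18 genes were apart in opposite directions. Cyp4p1, CG15385 and swi2, each under the floor without PI3K on at least 1 array, were at least 2.01, 2.96 and 1.86 log2 higher with it in Hdac3-depleted discs. CG10912, under the floor with both transgenes, was lower with PI3K in both Hdac3 states (-1.58, and -1.38 as a bound). It was also lower with Hdac3 RNAi in both PI3K states (-1.45, and -1.25 as a bound). For the Hdac3 effect, CG9021 (2.95 and 2.17) and Rnf11 (1.15 and 1.84) were higher in both, against 0.0666 for lists of 18 and 27. In all, 8 genes were apart in the same direction for the Hdac3 effect and 8 in opposite directions. For the PI3K effect, 4 were apart in the same direction, fewer than the 18 in opposite directions. Genes that vary widely between arrays can enter both lists in either direction. An excess over independent lists therefore does not by itself show a repeated effect. With the mean over its 2 probe sets, Rnf11 had 0.83 and 1.12. Lower in both were Ect3 (-2.34 and -1.55), AsnS (-1.63 and -1.27), Cpr64Ac (-1.57 and -2.66), CG7900 (-1.20 and -1.19), the spindle-orientation adaptor insc (-1.17 and -1.14) and Cyp18a1 (-1.01 and -1.10), 6 genes against 0.167 for lists of 20 and 61. AsnS had 195 and 189 without Hdac3 RNAi and 62.8 and 78.3 with it. The ratios of the PI3K effect correlated across genes with Spearman rho 0.40 (Pearson r 0.08) and those of the Hdac3 effect with rho 0.46 (r 0.28), and with gene span and level taken out rho was 0.33 and 0.44.

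**Figure D3:**
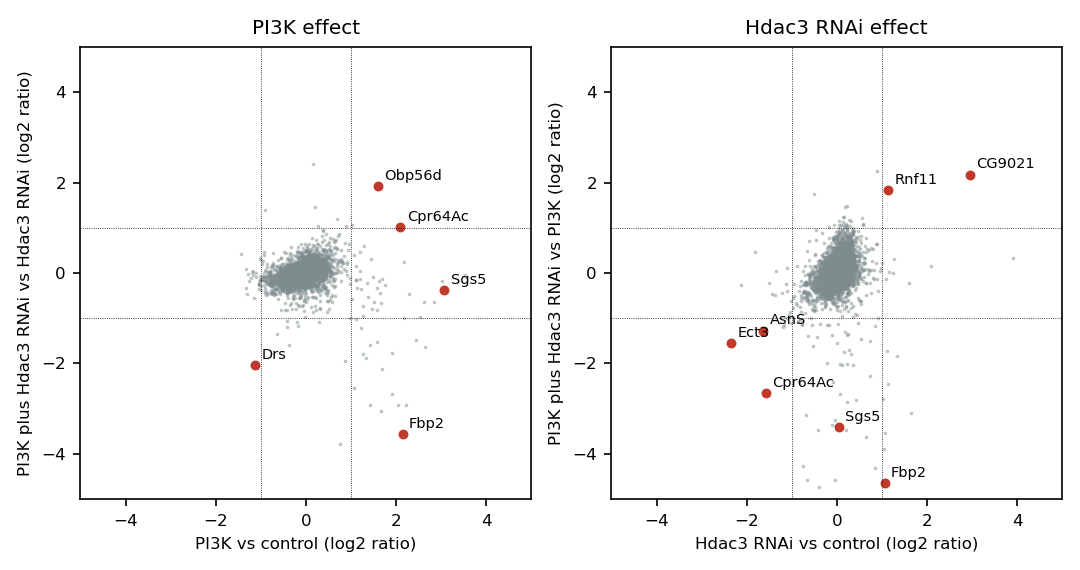
Log2 ratios of 7301 genes in contrasts without a shared array, 1 point per gene: the PI3K effect without and with Hdac3 RNAi (left) and the Hdac3 RNAi effect without and with PI3K (right). Obp56d is high on both axes at left (1.61 and 1.92) and AsnS low on both axes at right (-1.63 and -1.27).

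**Figure D4:**
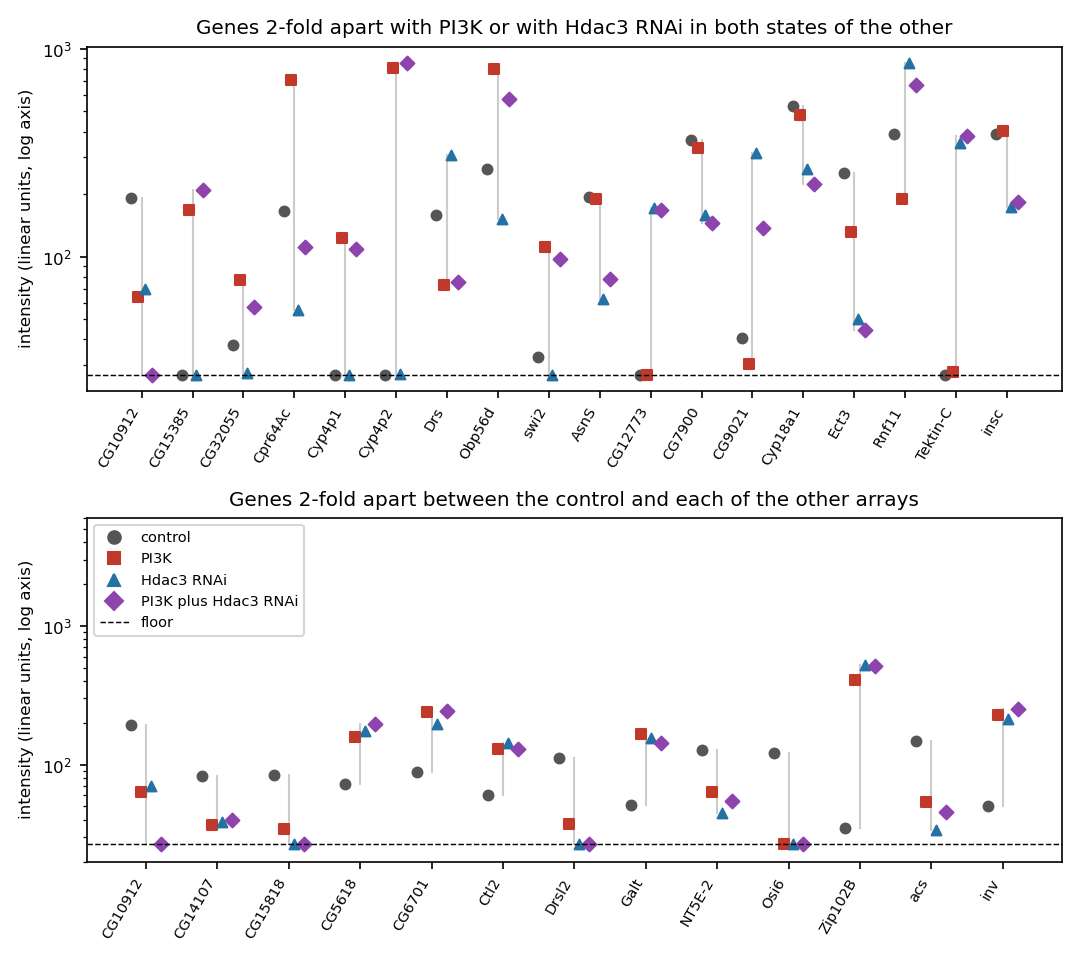
Intensity on a log scale on the 4 arrays of genes that follow a transgene or set the control array apart. Cyp4p2 is high with PI3K (806 and 859), Tektin-C with Hdac3 RNAi (350.4 and 382), and inv is low in control only (49.99).

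The additive limma model called Cyp4p2 for PI3K (coefficient 4.94 log2, Benjamini-Hochberg adjusted p 0.00664) and, for Hdac3 RNAi, Tektin-C (3.74, adjusted p 0.018) and CG12773 (2.65, adjusted p 0.0286), each higher on both arrays with the transgene. At an unadjusted p under 0.05 it listed 817 genes for PI3K and 1193 for Hdac3 RNAi, where 384.8 were due by chance among 7696. CG15385 (2.80), Cyp4p1 (2.10) and swi2 (1.80) had an adjusted p of 0.0757 for PI3K. With 1 residual degree of freedom these p-values rest on the prior variance shared across genes. Each of these 6 genes was raised to the floor on at least 1 array without the transgene, which can shrink both the coefficient and the residual, so its p-value does not carry the spread of its own signal.

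The effects of PI3K and Hdac3 RNAi departed from additivity at least 2-fold for 90 of 7301 genes, 21 above and 69 below. Furthest below were Fbp2 (-5.71), Obp99b (-5.15), CG34166 (-4.95), Fbp1 (-4.73) and Lsp2 (-4.60). Furthest above were krimp (2.29), CG33333 (2.25), acs (1.87), Sema1a (1.41) and CG11854 (1.39). Next came Hsp68 (1.36), plum (1.33), NT5E-2 (1.29) and Imp (1.27, or 0.89 as the mean of its 4 probe sets). Krimp had 215 in control, 115 with PI3K, 61.1 with Hdac3 RNAi and 160.1 with both. The glutamine synthetase gene Gs1 was at -1.32. Among lists, FOXO-responsive genes (0.28, percentile 99.99), wing patterning (0.20, percentile 100), E(spl) genes (0.30, percentile 99.9), anterior genes (0.34, percentile 99.9), PI3K and TOR components (0.18, percentile 99.8), adult muscle precursor markers (0.24, percentile 98.6) and G2 and mitosis (0.10, percentile 98.7) lay above additivity. Below it, besides fat body markers, lay mitochondrial ribosomal proteins (-0.14, percentile 0), proteasome (-0.10, percentile 0.01), glycolysis (-0.16, percentile 0.03), oxidative phosphorylation (-0.08, percentile 0.03), amino acid genes (-0.12, percentile 0.36), glutathione S-transferases (-0.08, percentile 1.395) and hemocyte markers (-0.27, percentile 0). Longer genes had higher departures (rho 0.35 with gene span). Matched on span, 10 of the 15 lists stayed outside the central 95%, while wing patterning (94.4), anterior genes (94.5), PI3K and TOR components (95.8), adult muscle precursor markers (86.9) and glutathione S-transferases (13.35) did not. For 11 genes with a PI3K main effect of at least 2-fold the median departure, signed by that effect, was -1.09, against -0.24 to 0.09 for random lists, and 6 of 11 were negative. The median is the value of Cpr64Ac and depends on which genes are kept. Fat body and glue genes are 3 of the 11, and without them the median over 8 genes was 0.17. Zip102B (-3.58) and inv (-1.94), which set the control array apart, were negative as well. The random lists were matched on level and not on effect size. The PI3K array, whose pairs had the largest SD of log2 differences, enters the main effect and the departure with opposite signs. Noise on that array alone would make the signed median negative. The value therefore does not show a smaller PI3K effect with Hdac3 RNAi. With 1 array per genotype, the departure holds noise and interaction together.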

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

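The tests of fat body carry-over, of RNA integrity and of the PI3K effect in Hdac3-depleted discs were chosen after the results were seen. Those of gene span and of the transgene chromosomes had predictions written before their own results. Matching on gene span was itself added after the list results were seen.

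The PI3K effect on fat body markers was 1.68 log2 without Hdac3 RNAi and -2.32 with it, a difference of -4.01, and the Hdac3 RNAi effect on them was 0.94 without PI3K and -2.93 with it, a difference of -3.87. The opposite signs make them stand out, and the differences were not tested. Across 9 members the ratio of the PI3K to the Hdac3 RNAi array had an SD of 1.04 log2 (0.62 without Obp44a), which does not decide on one fat body source of constant make-up because the spread between single preparations is unknown. Of 10 measured members, 7 were at least 2-fold higher in PI3K discs than in discs with both transgenes, and the list lay at -1.24 with both against control. Larval tissue carried over in dissection could give this. A response of disc cells to PI3K that Hdac3 depletion returns to the control level would put the list near 0 in both Hdac3-depleted genotypes. Against control the list lay at 0.94 with Hdac3 RNAi alone and at -1.24 with both. However, the spread between single preparations is unknown, and with 1 array per genotype the explanations cannot be told apart. Sgs3, Sgs4 and Fbp1 are also in the list of ecdysone response and staging, and larval age within the 3rd instar was not compared.

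E(spl) genes, targets of Notch, were lower with PI3K alone (-0.17) and higher with PI3K in Hdac3-depleted discs (0.16). The opposite signs make them stand out, and the difference of 0.32 was not tested.

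Metabolic lists were higher and patterning lists lower in the PI3K array. Matched on gene span, 6 of 8 higher lists stayed outside the central 95% of random lists. This argues against gene span bias as their whole cause, but transcript length and probe position were not matched. Of the lower lists, 3 of 8 stayed outside (PI3K and TOR components, wing patterning and E(spl) genes), so span bias may account for the others. The 16 lists leave out tissue markers; the hemocyte and both muscle lists stayed outside too, which makes 6 of 11 lower lists in all. The 3' to 5' ratio of the PI3K array lay below the range of the other arrays for 4 of 4 mRNA controls, with actin and Act5C both among them. With 1 such array, RNA integrity cannot be told apart from genotype. Matched on gene span, 6 of these 16 lists were outside random lists in the same direction in PI3K plus Hdac3 RNAi against Hdac3 RNAi (10 on level alone) and 1, the E(spl) list, in the opposite direction; of the 9 that stayed outside in PI3K against control 4 did so, and a PI3K effect stays open.

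Genes that follow a transgene on and off might lie on the chromosome of the transgene stock and differ by descent. Of 9 genes following PI3K, 6 (66.7%) lie on chromosome 2, against 38.1% of 7655 other genes (Fisher's exact test, two-sided, p 0.0933). Of 11 following Hdac3 RNAi, 5 (45.5%) lie on chromosome 3, against 44.4% of 7653 (Fisher's exact test, two-sided, p 1). CG10912 on chromosome 2 and Cpr64Ac on chromosome 3 are counted in both sets. With so few genes neither test settles the question, and a response to the transgene stays open.

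Probe sets without a gene name, which no comparison used, also held differences: 14 were at least 2-fold higher in PI3K discs than in control and 16 lower, of 1341 above the floor on both. They stand out as signal in data left out of the gene comparisons.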

How the results depend on the processing

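The count without fat body, glue and digestive genes, the lists matched on gene span and the FOXO-responsive list without Atg13 were added after the results were seen. Of 120 counts and summaries under the alternatives, 97 kept their direction and stayed within the margin of 1.5 times; of 590 values for named genes 540 did so, and of 1110 list medians 1028. Of 97 list percentiles 68 stayed outside the central 95% when random lists were matched on gene span, and without Atg13 the FOXO-responsive list kept its side of these bounds in all 6 contrasts. Of 97 list medians outside the central 95% of random lists, 0 took the other sign under quantile normalisation or no scaling. Removing the floor admitted low signals and raised counts: 33 genes higher with Hdac3 RNAi, 35 higher and 65 lower with both transgenes against control, 107 lower against PI3K, 18 higher and 55 lower against Hdac3 RNAi, and 134 below additivity. It also gave 9 higher and 2 lower genes for the PI3K effect in both Hdac3 states, 4 and 11 for the Hdac3 effect, and 2 limma calls for PI3K. The floor at the 40th percentile gave 5 higher and 2 lower genes for the PI3K effect in both states. The mean of probe sets left 1 gene higher for the Hdac3 effect. The median departure from additivity of PI3K-responsive genes was -0.50 with no scaling, -0.18 with the lower floor and -0.32 with no floor. It reversed to 0.17 without fat body, glue and digestive genes, which are 3 of its 11 genes. Zip102B and inv, not among these, were negative as well. The P450 list with both transgenes against control reversed to 0.0076 with no floor. For the Hdac3 effect limma called 1 gene with quantile normalisation and 1 with no scaling, and for PI3K 5 with an intensity trend in the prior. Except where stated, the cause was not tested. No paired analysis was possible because each genotype has 1 array, and leaving out an array ends a comparison. Signal over background limits genes near the floor of 26.9: ratios against a value under it are bounds, and those against a value just above it are kept as ratios.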

Other observations

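The test of X-linked genes was planned before its result was seen, and the other values in this part were picked after they were seen.

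A few genes followed 1 transgene whether or not the other was present. Asparagine synthetase (AsnS) and the ecdysone hydroxylase gene Cyp18a1 were lower in both Hdac3-depleted genotypes, and Obp56d and Cyp4p2 were higher in both PI3K genotypes, each beside the genotype that differs from it by that transgene alone. Cpr64Ac, a cuticle protein gene, followed both: 165 in control, 707 with PI3K, 55.5 with Hdac3 RNAi and 112 with both.

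Histone H4 acetylation at the residue named in the series title marks the male X chromosome in flies, so depletion of Hdac3 could shift X-linked genes as a set. The 1296 X-linked genes had a median log2 ratio of -0.03 with Hdac3 RNAi against control, at percentile 21.15 of 2000 random lists (-0.04 to -0.02), and 1308 X-linked genes had -0.03 with Hdac3 RNAi in PI3K discs, at percentile 74. A shift of X-linked genes as a set was not seen in these arrays, whose discs are of a sex not given in the sources used here.

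Of 100 marker control probe sets on the arrays, which read sequences used in transgenes and cloning, 10 were above the floor on an array and 2 of these were at least 2-fold apart between arrays. Both were lowest in the PI3K array. One was under the floor there, against 47.26 in control, 51.95 in Hdac3 RNAi and 66.37 with both transgenes. The other had 48.36 there, against 151.8, 148.1 and 209.9 in the same order. Whether this bears on the genotype of the PI3K array was not tested.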
